A study of Mus musculus with 6 samples.

How the data were processed

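RNA was extracted with Trizol and made into libraries with a SMARTer mRNA-seq kit, per the labels' protocols. The samples were 6 libraries of mouse bone marrow macrophages, 3 treated with RANKL and 3 with RANKL+NVP-BHG712, and groups and replicate numbers were read from the sample titles. StringTie and the genome build mm10 are named in the submitters' processing notes, without roles or versions. The aligner, the counting tool, the annotation, strandedness and the rule that chose the genes in the tables are not given in the sources used here.

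The authors deposited raw counts per gene for the 6 libraries in a single table, per the file headers. The authors also deposited FPKM values, in a table for each group, per the file headers. All held the same 2807 genes. Columns carried a letter and a number. The letters of the FPKM columns were tied to a group by the name of the table they stand in, the count columns share those letters, and the number was taken as the replicate number of the titles. Symbols matched GENCODE M21 (GRCm38, the assembly that mm10 names) for 2475 rows, and 290 rows were unnamed loci with a running number. Coordinates are those of GENCODE M21 genes.

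Table totals were not used as depth, because the table holds selected genes. The depth of each library was computed from the ratio of count to FPKM times transcript length, as the median over 126 genes with a single GENCODE transcript of at least 500 bp and at least 50 counts in each library. The 5th and 95th percentiles over these genes lay within 0.69% of the median. The depth so found is the total by which the authors divided, whatever reads it counts. It was 43.4, 43.5 and 41.7 megareads for RANKL replicates 1 to 3 and 44.5, 45.2 and 41.8 megareads for RANKL+NVP-BHG712 replicates 1 to 3.

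Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, group as the only term), with the recovered depth as the library size, the filterByExpr filter with its minimum count of 10, and Benjamini-Hochberg adjustment over the 2432 genes kept. An adjusted p under 0.05 was called a change. The design fixed before the data were examined had named TMM factors. These assume that most genes do not change, which a table of changed genes cannot meet, so the depth was put in their place after the table had been examined, and TMM is given as an alternative. The standard error of a log2 fold change is its size divided by the square root of F.

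The 26 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. Lists with at least 5 tested members, 16 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the 16. With the correlation estimated from the data none of the 7 called lists held, and the lowest adjusted p was 0.275. Since the table holds selected genes, a list is compared with other selected genes, and no enrichment against all expressed genes was computed. FPKM were tested with limma (trend) on log2(FPKM + 1), for genes with a group mean above 1. Fold changes on that scale understate the change of low genes, and those printed come from the counts.

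The naming rule took 17 genes chosen in advance (13 were in the table), the 6 largest increases and 6 largest decreases among called genes with separated groups, a mean of at least 5 CPM and a gene symbol, and up to 4 members of each called list or 2 of each other list with the smallest adjusted p. Unnamed loci were treated as having no symbol: 105 of the 227 tested rose and 109 fell. Genes named outside the rule were chosen after their values were seen. The values of a gene that the rule names are not reported here.

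The fits were tested on simulated data: counts for the 2432 genes, drawn from the real means and depths, with 200 genes changed. In the simulated comparison of the groups, edgeR recovered 25.8% of genes changed by 0.5, 70.1% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, and 4 of its calls were false. A simulated shifted list was called and 0 of 19 other lists were. The simulated genes were drawn independently of each other, so this does not test how camera treats lists whose genes vary together. The correlation estimated for the fixed lists reached 0.57, in cholesterol biosynthesis. Between replicates of a group the chi-square, averaged over genes, was 25.7 to 80.7 times that of sampling noise, so no library was a copy of another. A given relative difference weighs more in this average for genes with high counts, so it does not describe a typical gene.

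Alternatives were DESeq2 1.42.0 with its own size factors, limma-voom, RLE and upper-quartile factors, the table total as library size, no filter or a filter of 1 CPM in 3 libraries, an adjusted p under 0.01, a minimum change of 1, the replicate number as a block, and leaving out each library. Added after seeing the data were TMM on the table, a scaling to the midpoint of the empty interval, DESeq2 with the recovered depth, and Fisher's exact test of direction for lists. Tests in the closing section used Python 3.11.15 with scipy 1.17.1 and random gene sets drawn 10000 times.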

Results

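Bone marrow macrophages (BMMs) of wild-type mice, grown from marrow with the growth factor M-CSF, were profiled by RNA sequencing during their differentiation into osteoclasts, the multinucleated cells that resorb bone. After 3 days in M-CSF, the cells received the osteoclast-inducing cytokine RANKL for 2 days, either alone or together with NVP-BHG712, a small molecule known as an inhibitor of the EphB4 receptor tyrosine kinase. Each group held 3 libraries, and the labels state no dose. The comparison asked how the compound altered gene expression in RANKL-treated cells, in a study about its effect on osteoclast formation. No label says that the 3 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

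The deposited count table held 2807 genes and between 7102619 and 10269400 counts per library. These totals were a part of each library. The depth implied by counts and FPKM together was 41.7 to 43.5 megareads in the RANKL libraries and 41.8 to 45.2 megareads in the RANKL+NVP-BHG712 libraries. The table took 17.01% to 17.05% of the depth in the RANKL libraries and 21.7% to 22.7% in the treated libraries. No gene in the table had a ratio between groups close to 1. At equal depth the smallest increase was 0.74 and the smallest decrease -1.26 on the log2 scale, which leaves an empty interval centred on -0.26 and reaching 1.00 to either side. Such an interval would follow from a limit of 1 on the log2 scale under a scaling offset from the depth used here, and scaling to its midpoint moves the log2 fold changes up by 0.26. The table thus held genes selected for their change, the selection rule is not given in the sources used here, and passing a test in it is not independent evidence of a change. Genes outside the table are described as not analysed here.

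**Figure D1:**
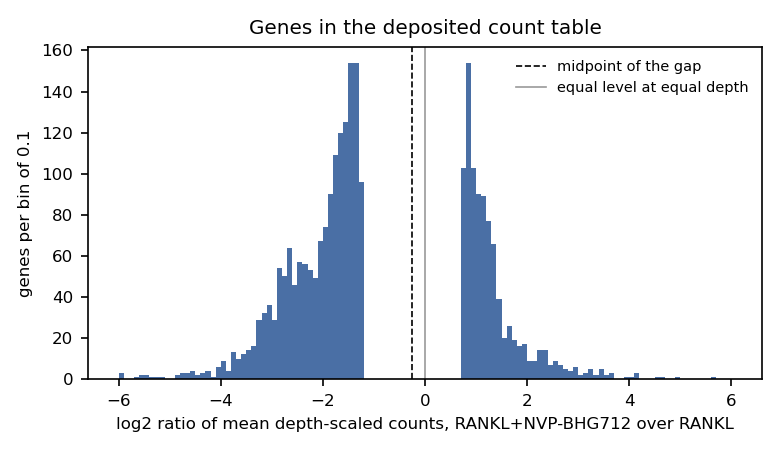
Histogram of the log2 ratio of mean depth-scaled counts, RANKL+NVP-BHG712 over RANKL, for the genes of the deposited table with counts in both groups. The horizontal axis is the log2 ratio, with values beyond the axis limits placed in the outermost bins, and the vertical axis the number of genes per bin of 0.1. No gene lies between -1.26 and 0.74, and the dashed line marks the midpoint of that interval at -0.26.

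More of these genes were lower than higher with NVP-BHG712. Of 2432 genes with enough counts for testing, 1561 were lower and 817 higher with the compound at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and 54 did not pass. A change of at least 2 on the log2 scale was seen in 646 of the lower and 69 of the higher genes. In this table of selected genes, log2 CPM values correlated across genes at 0.982 to 0.988 within groups and 0.845 to 0.872 between groups, and the first principal component, which separated the groups, held 89.9% of the variance.

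The balance of higher and lower genes depended on the scaling, because the table held selected genes only. The values here use the depth of each library. TMM factors computed on the table moved the log2 fold changes up by a median of 1.04 and gave 871 higher and 1092 lower genes. RLE factors in edgeR and the size factors of DESeq2, which place the middle of the table at no change, moved them up by 1.36 each. They gave 871 higher and 701 lower genes, and 869 higher and 678 lower genes, respectively. The sizes turned round with them: with RLE factors a change of at least 2 was seen in 90 lower genes and in all 871 genes called higher. Smaller or more variable decreases lost their call or their sign under these latter scalings, and the number of calls that stayed is given beside each group. These scalings put the middle of a table of changed genes at no change, so a call lost under them does not decide whether a gene fell.

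Ephb4, the transcript of the kinase that the compound is known to inhibit, was scarce and lower in treated cells. Its level was 0.303 ± 0.046 FPKM with RANKL (SD, n = 3) and 0.099 ± 0.065 FPKM with RANKL+NVP-BHG712 (SD, n = 3). The counts were 47, 62 and 60 against 6, 32 and 19. The log2 fold change was -1.60 (SE 0.48, adjusted p = 0.0102). Ephb4 lies on chromosome 5 from 137350109 to 137378669 (GRCm38), and some of its exons overlap another annotated gene. The call ended with upper-quartile factors (log2 fold change -0.79, adjusted p = 0.14), with TMM factors on the table (-0.56, adjusted p = 0.28), with RLE factors (-0.25, adjusted p = 0.70) and with DESeq2's own size factors (-0.26, adjusted p = 0.73). All 7 Eph receptors and ephrins in the table were lower, out of 22 listed, among them Ephb2 (-2.02), Ephb3 (-2.98) and Epha2 (-1.55). The ligand genes Efnb1 and Efnb2 fell from 3.93 ± 0.18 to 1.40 ± 0.31 FPKM and from 0.962 ± 0.073 to 0.397 ± 0.012 FPKM. As a list they did not stand apart from the other genes of the table (camera adjusted p = 0.216). Under RLE factors and under DESeq2's own size factors none of the 7 stayed called, and Efnb2 changed sign. With TMM factors 3 of the 7 stayed called, and Ephb2, Epha2 and Efnb2 were among those that did not. With upper-quartile factors 4 did, and Ephb2 and Epha2 were again among those that did not.

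Transcription factors that drive osteoclast differentiation fell together. All 8 of the 8 tested members were lower, out of 22 listed, with a median log2 fold change of -2.43 (camera adjusted p = 0.038; adjusted p = 0.275 with an estimated correlation). Fisher's exact test of direction against the rest of the table, chosen after seeing the data, did not call the list (adjusted p = 0.114). Nfatc1, the master regulator of the lineage on chromosome 18 (80606205 to 80713071), fell 2.67-fold from 35.1 ± 6.0 to 13.2 ± 0.83 FPKM. Fos, an AP-1 subunit required for osteoclast formation, fell 6.05-fold from 125 ± 7.0 to 20.7 ± 1.4 FPKM. Jdp2, another AP-1 family member, fell 13.3-fold from 214 ± 15 to 16.1 ± 1.3 FPKM. Fosl2 and Myc fell 5.44-fold and 5.37-fold. With RLE factors and with DESeq2's own size factors 5 of the 8 stayed called, and Nfatc1 lost its call, at a log2 fold change of -0.063 under each (adjusted p = 0.75 and 0.77) against -1.42 with the library depth.

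Genes of mature osteoclasts were mostly lower, with exceptions among subunits of the vacuolar proton pump. In the list of bone resorption machinery 7 of 8 tested members fell, out of 36 listed. Mmp9, a matrix metalloproteinase, fell 4.27-fold from 906 ± 60 to 212 ± 15 FPKM. Acp5, which encodes tartrate-resistant acid phosphatase, fell 2.96-fold from 395 ± 39 to 134 ± 9.5 FPKM, and Ctsk, the collagen-degrading cathepsin K, fell 2.65-fold from 389 ± 41 to 147 ± 13 FPKM. The receptor genes Oscar and Calcr fell 4.78-fold and 3.69-fold. Atp6v0a1, a subunit of the proton pump, rose 3.28-fold from 63.7 ± 7.1 to 213 ± 1.3 FPKM. Of 11 tested fusion genes, 8 fell and 3 rose, out of 18 listed. Ocstamp, a membrane protein needed for cell fusion, fell 10.2-fold from 10.4 ± 0.75 to 1.02 ± 0.10 FPKM, Dcstamp fell 2.56-fold, and Slc9b2, a sodium and proton exchanger, fell 7.51-fold. Atp6v0d2, a proton pump subunit also linked to fusion, rose 2.21-fold from 238 ± 18 to 526 ± 3.9 FPKM, and the other two that rose were Cd9 and Rbpms, named here after their values were seen. Neither list differed from the rest of the table (camera adjusted p = 0.216 and 0.543). With RLE factors and with DESeq2's own size factors 4 of the 7 lower resorption genes and 5 of the 8 lower fusion genes stayed called. Acp5, Ctsk, Dcstamp and Calcr lost their calls, and 1 more fusion gene lay above 0.

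**Figure D2:**
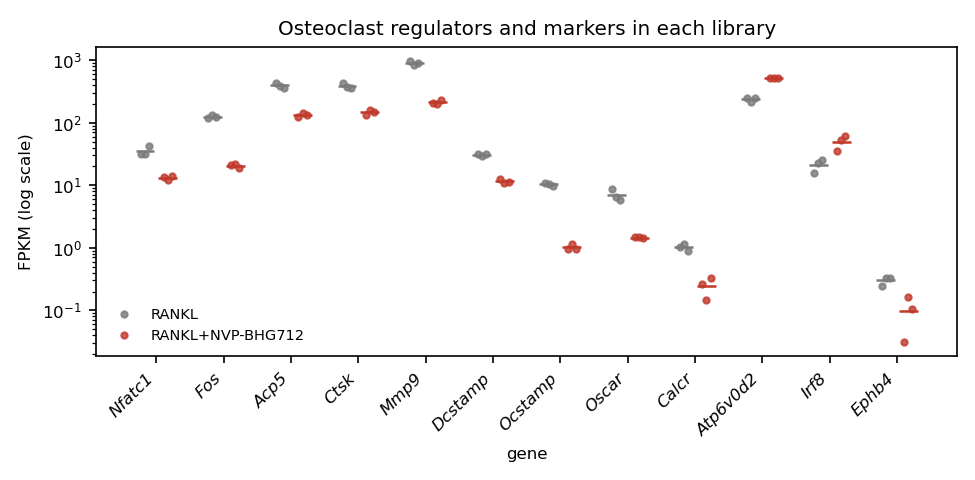
FPKM (logarithmic vertical axis) of osteoclast regulators and markers, by gene along the horizontal axis. Each point is a library, grey for RANKL and red for RANKL+NVP-BHG712, and short lines mark the means of 3 libraries. Mmp9 lies at a mean of 906 FPKM with RANKL and 212 FPKM with the compound, whereas Atp6v0d2 and Irf8 are higher with the compound. The plotted FPKM are the authors' values and carry the same library depth as the main fit. The distance between the groups would differ under the other scalings, which are not plotted.

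Repressors of osteoclast differentiation moved in both directions, with 4 higher and 3 lower of 7 tested and 18 listed. Irf8 rose 2.33-fold from 21.4 ± 5.2 to 49.7 ± 13 FPKM and Maf rose 2.58-fold. Nfkbia, the inhibitor of NF-kappaB, fell 2.70-fold and lost its call with RLE factors and with DESeq2's own size factors, which left 1 and 2 of the 3 lower genes called. The median of the list was 0.74 and its mean -0.15. Camera, which compares it with the other genes of the table, placed it upward without a call (adjusted p = 0.321). The rotation test fry, which compares it with no change, placed it downward (adjusted p = 0.0247). In RANK and M-CSF receptor signalling, 2 of 38 listed genes were in the table, and both were higher: Trem2, from 351 ± 20 to 684 ± 42 FPKM, and the kinase gene Tec, from 20.5 ± 0.88 to 36.1 ± 0.43 FPKM. Itgb3, Tnfrsf11a, Csf1r and Bcl6 were not analysed here.

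Cell-cycle genes fell. All 40 tested members were lower, out of 44 listed, with a median log2 fold change of -2.87 and a range from -3.57 to -1.55 (camera adjusted p = 8.0e-07; adjusted p = 0.308 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells, fell 9.40-fold from 119 ± 5.1 to 12.7 ± 0.16 FPKM. Bub1, a mitotic checkpoint kinase, fell 9.03-fold, Cenpf 8.53-fold and Ccna2, which encodes cyclin A2, 7.87-fold. Ccnd1, the cyclin D1 gene in the list of MAPK feedback genes, fell 7.67-fold from 111 ± 15 to 14.5 ± 1.7 FPKM. That list had 3 lower genes and 1 higher gene in the table, out of 23 listed, and the higher gene was Atf3 (117 ± 12 to 239 ± 7.0 FPKM). Of its lower genes Ccnd1 alone stayed called with RLE factors and with DESeq2's own size factors, and 39 of the 40 cell-cycle genes did. In the list of p53 and apoptosis genes 5 rose and 2 fell of 7 tested and 29 listed (camera adjusted p = 0.102). Sesn1, a stress-induced regulator of growth signalling, rose 2.25-fold, and Cdkn1a, which encodes the cell-cycle inhibitor p21, fell 2.40-fold. Neither lower gene stayed called with TMM or RLE factors on the table or with DESeq2's own size factors, and Cdkn1a changed sign with RLE factors and with DESeq2's own size factors. With RLE factors the list itself passed upward (adjusted p = 0.0496).

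Lysosomal genes rose, and they were among the most abundant transcripts in the table. All 13 tested members were higher, out of 33 listed, with a median log2 fold change of 1.00 (camera adjusted p = 5.2e-06; adjusted p = 0.275 with an estimated correlation). Psap, the precursor of the saposins on chromosome 10 (60277627 to 60302597), rose 2.63-fold from 3463 ± 249 to 9124 ± 139 FPKM. The proteases Ctsd and Ctsb rose 2.49-fold and 2.43-fold, and Gabarapl1, an autophagosome protein, rose 2.10-fold. The 10 genes with the highest mean count in the table were all higher with the compound. Gpnmb, Psap, Ctsb and Ctsd are in the lysosomal list, whereas Fth1, Apoe, Mpeg1, Lgals3, Cd36 and Itm2b are not. Together these 10 genes took 4.85% to 5.19% of the depth with RANKL and 10.8% to 11.9% with the compound. They were chosen over the 6 libraries together, not within each library or group.

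Genes of cholesterol and lipid handling and markers of macrophages also rose. All 10 tested members of the cholesterol biosynthesis list were higher, out of 25 listed, with a median of 1.09 (camera adjusted p = 2.6e-05; adjusted p = 0.308 with an estimated correlation). Insig1, a sterol sensor, rose 2.47-fold from 30.4 ± 1.8 to 75.03 ± 1.4 FPKM, and the pathway enzymes Sc5d, Mvd and Hmgcs1 rose 2.40-fold, 2.33-fold and 2.16-fold. Of 13 tested genes of cholesterol efflux and lipid storage, 12 rose and 1 fell, out of 24 listed (camera adjusted p = 2.3e-05; adjusted p = 0.275 with an estimated correlation). The fatty acid binding proteins Fabp4 and Fabp5 rose 4.93-fold and 2.46-fold, the desaturase Scd2 rose 3.19-fold and the nuclear receptor Pparg 2.44-fold. The member that fell was Dgat2 (log2 fold change -1.59), named here after its value was seen, and its call ended with TMM and RLE factors on the table and with DESeq2's own size factors. All 8 tested macrophage markers were higher, out of 31 listed, with a median of 1.24 (camera adjusted p = 5.9e-05; adjusted p = 0.275 with an estimated correlation). Cd5l, a secreted macrophage protein, rose 5.07-fold from 9.01 ± 0.44 to 45.7 ± 2.4 FPKM. The Fc receptor gene Fcgr3 rose 2.80-fold, and the complement gene C1qc and the mannose receptor gene Mrc1 rose 2.36-fold each.

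Interferon-stimulated genes fell. All 14 tested members were lower, out of 38 listed, with a median log2 fold change of -1.84 (camera adjusted p = 0.0204; adjusted p = 0.413 with an estimated correlation). With RLE factors and with DESeq2's own size factors 6 of the 14 stayed called, 2 lay above 0 without a call and the median was -0.48. Rtp4 fell 5.40-fold from 23.3 ± 3.9 to 4.53 ± 0.92 FPKM, Isg15 4.47-fold, Irf7 4.01-fold and Oasl2 2.94-fold. Oasl2 was among those that lost their calls. Among inflammatory cytokines and chemokines 6 rose and 4 fell of 10 tested and 32 listed (camera adjusted p = 0.0707). The rise of Il18 (log2 fold change 0.77), named here after its value was seen, was weakly held. Its call in edgeR ended without a filter (adjusted p = 0.0586), with the table total (adjusted p = 0.283) and without several single libraries. The chemokine gene Ccl3 rose 5.48-fold from 5.71 ± 0.77 to 31.3 ± 1.6 FPKM. Ccl9 fell 2.44-fold from 283 ± 1.3 to 116 ± 1.2 FPKM and changed sign, without passing the threshold, with RLE factors and with DESeq2's own size factors, under which none of the 4 lower genes stayed called. In the list of the unfolded protein and integrated stress responses 7 fell and 1 rose of 8 tested and 35 listed (camera adjusted p = 0.247). Of the 7, 5 stayed called with TMM factors on the table and 4 with RLE factors and with DESeq2's own size factors. The amino acid transporter gene Slc7a5 fell 11.5-fold from 18.6 ± 2.1 to 1.61 ± 0.26 FPKM and Shmt2, a mitochondrial enzyme of one-carbon metabolism, fell 5.10-fold. The member that rose was Ddit3 (log2 fold change 0.82), named here after its value was seen.

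**Figure D3:**
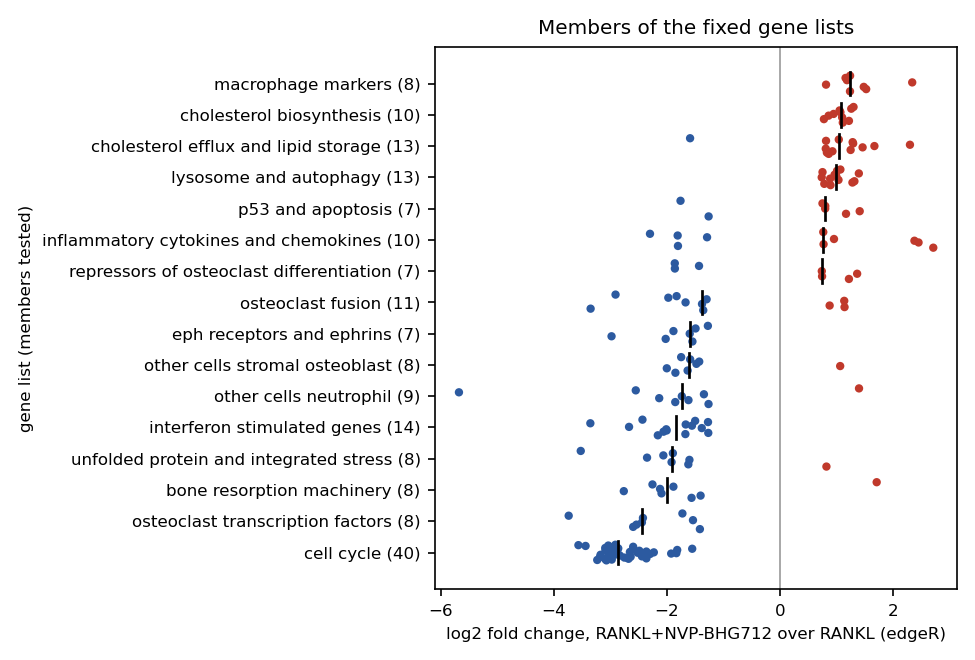
Log2 fold change, RANKL+NVP-BHG712 over RANKL (horizontal axis, edgeR with library depth), of each tested member of the gene lists fixed before the data were examined (vertical axis, number of tested members in parentheses). Red points are higher and blue points lower with the compound, and the black bar is the median of the list. All 40 cell-cycle genes lie below 0, with a median of -2.87, and all 13 lysosomal genes lie above 0. RLE factors on the table put 2 of the 14 interferon-stimulated genes and 1 of the 7 Eph receptor and ephrin genes above 0, with 2 further neutrophil genes, 1 further fusion gene, Ccl9 and Cdkn1a.

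Markers of other cell types that a marrow culture can hold also differed between the groups. Of 9 tested neutrophil genes 8 fell and 1 rose, out of 17 listed (camera adjusted p = 0.148). Ltf, the lactoferrin gene, fell from 92.4 ± 8.9 to 21.2 ± 2.1 FPKM and the granule protein gene Ngp fell 3.07-fold from 353 ± 25 to 115 ± 11 FPKM, while the receptor gene Csf3r, named here after its value was seen, rose (log2 fold change 1.40). RLE factors put 2 further neutrophil genes above 0 and left the other 6 called. Of 8 tested stromal and osteoblast genes 7 fell and 1 rose, out of 20 listed (camera adjusted p = 0.271). Col1a2, a collagen gene of stromal cells, fell 3.10-fold from 34.6 ± 7.7 to 10.5 ± 1.1 FPKM and lost its call with RLE factors and with DESeq2's own size factors, which left 2 and 3 of the 7 called. Spp1, which encodes osteopontin and is also made by osteoclasts and macrophages, rose 2.09-fold. In the dendritic cell list Siglech fell, with counts of 43, 54 and 53 against 3, 0 and 3, and Clec10a rose 2.02-fold. Cd4 was the tested member of the lymphoid list and rose 5.80-fold from 5.70 ± 0.25 to 33.1 ± 5.8 FPKM. Gata2 was the tested member of the erythroid, megakaryocyte and mast cell list, and it fell 3.02-fold, a call that ended with TMM and RLE factors on the table and with DESeq2's own size factors.

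Energy metabolism was hardly represented in the table. Glycolysis and hypoxia had 2 of 27 listed genes, Ndrg1, which rose 2.42-fold, and Gapdh, which fell by 2.58 on the log2 scale. The counts of Gapdh in the RANKL libraries were 3573, 696 and 2768, against 418, 449 and 339 with the compound, and its call ended with RLE factors and with DESeq2's own size factors. Oxidative phosphorylation had 1 of 42 listed genes, Cycs, which fell 2.86-fold and lost its call under the same scalings. The 15 mitochondrially encoded genes had 1, mt-Atp6, which fell 7.86-fold from 1920 ± 63 to 244 ± 21 FPKM. Oxidative stress had 2 of 29 listed genes. Fth1, the ferritin heavy chain, was at 4575 ± 1312 FPKM with RANKL and 8625 ± 3231 FPKM with the compound (log2 fold change 0.89, adjusted p = 0.0122). Its call ended without RANKL+NVP-BHG712 replicate 2 (adjusted p = 0.0509) and with the table total as the library size (adjusted p = 0.101). Nox1, a superoxide-producing oxidase, had counts of 28, 29 and 17 against 7, 0 and 11 (log2 fold change -2.03, adjusted p = 0.0215). Its call ended with RLE, TMM and upper-quartile factors, with the replicate number as a block and with DESeq2's own size factors. The call also ended without RANKL replicate 1 (log2 fold change -1.94, adjusted p = 0.0542) and without RANKL replicate 2 (-1.91, adjusted p = 0.0751). It stayed without RANKL+NVP-BHG712 replicates 2 and 3, at log2 fold changes of -1.44 and -2.83. Antigen presentation had no gene in the table, and its 21 listed genes were not analysed here. In every fixed list the counts adjusted over the list alone equalled those adjusted over all genes tested.

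The largest decreases among genes with a mean of at least 5 CPM included growth factors of blood and lymph vessels. Pgf, the placental growth factor gene on chromosome 12 (85166635 to 85177790), fell 27.0-fold from 21.3 ± 2.5 to 0.729 ± 0.086 FPKM. Vegfc, a lymphatic growth factor gene, fell 18.0-fold from 9.01 ± 0.57 to 0.493 ± 0.053 FPKM. Mycl, a MYC family transcription factor, fell 16.6-fold and Gstt1, a glutathione transferase, fell 15.6-fold. H2-Q7 and H2-Q6, neighbouring non-classical MHC class I genes on chromosome 17, fell 22.4-fold and 20.9-fold. Their sequences are so alike that counting could split reads between them, so the value of each is uncertain. The largest increase was that of Mgll, which encodes monoacylglycerol lipase, on chromosome 6 (88724412 to 88828360). It rose 11.2-fold by counts, which were 906, 2171 and 1099 with RANKL, and 8.68-fold by mean FPKM, from 11.1 ± 2.3 to 96.0 ± 3.7. The count per FPKM of this gene varied between libraries, so the size of its rise is uncertain. Bex1 rose 8.26-fold, Dio2, which encodes a deiodinase that activates thyroid hormone, 7.67-fold, Cnrip1, which encodes a protein that binds the CB1 cannabinoid receptor, 7.61-fold, Ms4a4a 7.22-fold and Sorbs3 6.32-fold. All 12 passed at an adjusted p under 0.05 in edgeR and kept their calls and directions under the alternatives run on named genes.

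Counting errors from shared sequence could affect several of these genes, and such errors were not measured. Gapdh, Fth1 and mt-Atp6 have near-identical copies elsewhere in the genome, so their values are uncertain. Exons of Ephb4, Acp5, Jdp2, Maf, Ccnd1, Cdkn1a, Top2a, Ccna2, Irf7, Rtp4, Hmgcs1, Scd2, Ctsb, Ctsd, Gabarapl1, Shmt2, Spp1, Ndrg1, Nox1, Mgll, Bex1, Dio2, Cnrip1 and Sorbs3 overlap those of another annotated gene, and it is not known whether the counting used strand.

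The authors' FPKM gave the same directions as the counts. Of 1765 genes with a mean above 1 FPKM in either group, 641 were higher and 1094 lower at an adjusted p under 0.05 in limma on log2(FPKM + 1). Of the 1735 called genes, 1731 were also called from the counts, all 1731 in the same direction. Both kinds of value came from the same reads and the same selected genes. The depth used for the counts was itself computed from these FPKM, so the match in direction was largely fixed beforehand.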

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

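Scaling decided how many genes counted as lower. With DESeq2's own size factors 1547 genes were called (678 lower) and with RLE factors 1572 (701 lower), against 2378 (1561 lower) with the library depth. These factors set the middle of the table to no change, which moves the log2 fold changes by 1.36, and by their construction small decreases then lose their call. Of the called genes, 179 and 181 changed sign. Among named genes, Efnb2 reversed to 0.0808 and 0.0806, Ccl9 to 0.0677 and 0.0677 and Cdkn1a to 0.0955 and 0.0954, and 13 others lost their calls under each. EphB4 lost its call there, at -0.26 (adjusted p = 0.73) and -0.25 (adjusted p = 0.70), and also with TMM factors on the table, at -0.56 (adjusted p = 0.28), where Efnb2 (-0.23, adjusted p = 0.216), Cdkn1a, Nox1 and Gata2 lost theirs too. That last alternative, the midpoint of the empty interval and DESeq2 with the recovered depth were chosen after seeing the data. They called 1963, 2399 and 2329 genes and reversed none of the called genes. Upper-quartile factors, which shift values by 0.81, called 2185 (871 higher) and ended the calls of EphB4 (-0.79, adjusted p = 0.14) and Nox1 (-1.23, adjusted p = 0.13), for which they were added after seeing the data, and table totals, which shift them by -0.38, called 2235 (674 higher).

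Requiring a log2 fold change of at least 1 left 487 higher genes and all 1561 lower ones, since the table holds no smaller decrease. An adjusted p under 0.01 left 2165. Without a filter 2592 genes were called, with a filter of 1 CPM 1955 and with limma-voom 2357. Leaving out each library in turn gave 2317 to 2410 genes, 7 lists each time, and -2.16 to -1.17 for EphB4, whose lowest value came without RANKL+NVP-BHG712 replicate 2 and highest without replicate 1. Among the genes named by the rule, Fth1 and Nox1 lost their calls without single libraries. Of other list members, Il18 did so without RANKL replicate 1 or 3 and without RANKL+NVP-BHG712 replicate 2 or 3. Il10 and Twist1 did so without RANKL replicate 2, and Tyro3 without RANKL replicate 3.

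No fixed list was called by camera with the correlation estimated from the data (0 of 16). Fry, which does not compare a list with other genes, called 16, and placed the repressors of osteoclast differentiation downward where camera points upward (adjusted p = 0.0247). These directions do not conflict, because camera compares a list with the other genes of the table and fry compares it with no change. The mean log2 fold change of this list was -0.15, below no change but above the median log2 ratio of the table, -1.47. RLE factors called 8 lists, and Fisher's exact test of direction, chosen after seeing the data, 6, without the osteoclast transcription factors (adjusted p = 0.114).

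There was little sign that equal replicate numbers pair the samples, and the labels do not say whether they do. The deviations of same-numbered libraries from their group means correlated across genes at 0.003, 0.008 and 0.046. With the replicate number as a block 2324 genes (783 higher, 1541 lower), 7 lists, 1732 genes from FPKM and an EphB4 log2 fold change of -1.75 were obtained. Nox1 was the named gene that lost its call (adjusted p = 0.0601), at a log2 fold change of -2.16 against -2.03 without the block. RANKL replicate 1 correlated best with another number (0.039), and RANKL replicates 2 and 3 with their own.

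From FPKM, a pseudocount of 0.1 called 1735 genes, no filter 2477 and leaving out libraries 1717 to 1735. In the simulation, which varied neither depth nor spread, 25.8% of changes of 0.5 on the log2 scale were recovered. At the recovered depth the table holds no increase under 0.74 and no decrease smaller than -1.26. The simulation also changed 200 of 2432 genes, whereas nearly all genes of the table were called, so its shares do not carry over to them.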

Other observations

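Further gene groups, some of which share members with the fixed lists, moved as well. The lists in this part, and all tests in it except those over other splits of the libraries and the overlap of exons, were chosen after the data were seen. Fisher's exact test of direction counts the genes of a list as independent. With an estimated correlation between genes camera called no fixed list, and the lists added here were not tested in that way. Of a list of 40 ribosome biogenesis genes 28 were in the table, and all 28 fell, with a median log2 fold change of -1.56 (Fisher's exact test of direction against the rest of the table, adjusted p = 3.2e-05). With RLE factors 13 of the 28 stayed called and with DESeq2's own size factors 12, with a median of -0.20 under each and 1 gene above 0. Dkc1, a pseudouridine synthase subunit, fell by 2.58, and Nop56 and Nop58, core proteins of small nucleolar ribonucleoproteins, fell by 2.004 and 2.03 on the log2 scale. Of 26 genes of nucleotide and one-carbon synthesis 14 were in the table and all 14 fell (median -2.04, adjusted p = 0.0038), including Ctps (-2.83). Of 31 DNA repair genes 27 were in the table and all 27 fell (median -2.31, adjusted p = 3.2e-05), including Fancd2 (-3.19) and Brca1 (-2.61). With RLE factors and with DESeq2's own size factors 11 of these 14 and 22 of these 27 stayed called. These genes are also raised in dividing cells, and some overlap in function with the cell-cycle list.

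Other lists were mostly higher. Of 24 listed genes for the clearance of dying cells 12 were in the table, and 11 rose, led by Gas6 (log2 fold change 2.30), Stab2 (1.76) and Mertk (1.53), and Tyro3 fell (-1.53; adjusted p = 0.00019 for direction). Of these 12, 5 are also in the fixed macrophage list. Of 28 listed targets of FoxO transcription factors 12 were in the table, and 11 rose, among them Gadd45a (2.14), Pink1 (1.40) and Fbxo32 (1.35), and Klf4 fell (-1.70; adjusted p = 0.00019). The falls of Tyro3 and Klf4 lost their calls with RLE factors and with DESeq2's own size factors, and that of Tyro3 also with TMM factors, with upper-quartile factors and without RANKL replicate 3. All 8 tested targets of the oxysterol receptor LXR, out of 18 listed, rose (adjusted p = 0.00035), but all 8 also stand in fixed lists already described, so this adds no further genes.

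A hypothesis for the lysosomal rise is higher activity of the MiT/TFE transcription factors, which bind the promoters of lysosomal genes. Of 15 further known targets outside the fixed lists 8 were in the table, and all 8 were higher, including Mcoln3 (log2 fold change 2.04) and Rragd (1.92), with a Fisher's exact p of 0.00027 for direction against the rest of the table. Tfeb itself rose from 19.4 ± 1.0 to 33.6 ± 3.1 FPKM. These values are consistent with the hypothesis, but the list was drawn up after the lysosomal rise was seen, and targets outside the table were not analysed here. Trapping of a drug in lysosomes can raise the same genes and was not tested.

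Stromal genes fell with the compound. In the fixed stromal list and a wider list of 31 genes, 19 members fell by similar amounts, with a median log2 fold change of -1.59. With RLE factors 2 of the 7 lower genes of the fixed list and 3 of the 12 of the wider list stayed called, with medians of -0.25 and -0.14 over all tested members. The 19 were the tested members called lower. Spp1, the other tested member of the fixed list, rose by 1.07 and was left out for its direction, not for its cell type. Osteoclasts and macrophages also make Spp1. The SD of the log2 fold changes of the 19 was 0.24, against a median of 0.66 for random sets of lower genes. It lay at percentile 0.0 of 10000 sets matched on expression. A smaller share of stromal cells in the treated wells would give a low SD. So could the selection of genes, since the table holds no decrease smaller than -1.26 and these modest falls lie close to that limit. The sets were not matched on the size of the fall, so the SD does not decide between these. The same 19 genes deviated together in RANKL replicate 3, with a median of -0.267 from the group mean, below nearly all matched sets (percentile 0.0). Of the 19, 18 were lowest there among the RANKL libraries. This library was singled out after the data were seen, so the deviation is a description and not an independent test. A varying number of stromal cells per well may account for part of this group, which these values do not decide. The deviation within the RANKL group is small beside the median fall. An effect of the compound on these genes within cells, or on the survival of stromal cells, stays open.

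Among the neutrophil genes Retnlg fell most. The SD of the log2 fold changes of the 8 lower members was 1.44, at percentile 98.47 of matched sets, with Retnlg at -5.68. Without Retnlg the other 7 lay between -2.55 and -1.26, with an SD of 0.45 at percentile 22.05. A loss of neutrophil-lineage cells of unchanged makeup, which lowers all their genes by a common factor, is therefore neither supported nor excluded, because a single gene carries the spread of the lower members. Csf3r, a tested member outside them that is also expressed in monocytes, rose by 1.40, which such a loss alone does not give. A shift between maturation stages of such cells, or regulation within cells, stays open and was not tested.

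Some genes had a library out of line with its group, such as Gapdh with 696 counts in RANKL replicate 2. In the 50 genes with the largest spread within groups, of 1323 with sufficient counts, the within-group SD of log2 count per FPKM had a median of 0.046 against 0.0090 elsewhere (permutation p = 0.0001, the smallest that 10000 draws can give), so the transcript length implied by counts and FPKM also varied. That is consistent with reads assigned to different transcripts from library to library, but in 27 of the 50 the SD was under 0.05, small beside the median spread of 0.62 in their counts, so it is not the whole cause. Exons overlapped another gene in 45.7% of those 46 with a position and in 33.0% of the others (Fisher's exact p = 0.0808), which decides nothing. No biological explanation was tested.

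With 6 libraries there are 10 splits into groups of 3, so no share under 0.05 can be reached, and the table holds genes selected for their change between the real groups, which fixes the outcome for genes beforehand. These values therefore do not decide whether the grouping arose by chance. The real split gave 2378 genes from counts and the highest other split 1, and 1 of the 10 splits gave as many. From FPKM the real split gave 1735 genes and the highest other 2, and again 1 of the 10 gave as many. For the gene lists the real split called 7 and the highest other 6, and 1 of the 10 gave as many. Every other split still puts 2 libraries of a group against 1, so the number of lists called by camera with a preset correlation hardly separates the real split from the others.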
